A study of Mus musculus with 15 samples.

How the data were processed

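RNA was sequenced from optic nerves of adult C57BL/6J mice, per the labels, after injection of AAV2 carrying a secretable CNTF or of AAV2-null into the vitreous 2 weeks before crush, with collection 7 days after it, or before a sham operation whose times the labels do not give. The design gives 5 biological replicates in each of 3 groups, so they are taken as separate animals. Per the submitters' protocol notes, RNA was purified with RNeasy Micro columns and DNase, 2 library kits are named (Nugen AnyDeplete with 20 ng and TruSeq Stranded Total with 500 ng), and libraries were run on an Illumina NovaSeq. Which kit served which library is not given in the sources used here. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.32, aligned to mm10 with STAR 2.5.3a and quantified with RSEM 1.2.31, and R 3.2.3 and DESeq2, without a version, are also named. The gene annotation and DESeq2's settings are not given in the sources used here.

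The authors deposited 1 table of 14237 genes. Per the file headers it holds the RSEM expected count of each gene in each library, made by the authors from the aligned reads. It also holds FPKM values, fragments scaled by gene length and library depth, which the authors computed per library. The authors deposited a log2 fold change for each of the 3 pairs of groups, the first named group over the second. They also deposited an adjusted p-value for each pair, which the authors computed per gene. Each listed gene has an FPKM of at least 1 in at least 4 libraries of some group, so genes of low level are absent and library totals cover the listed genes only. The totals ran from 19856688 to 29558293 expected counts per library, and 13.7% to 18.3% of expected counts were not whole numbers and were rounded. Counting error of reads is small at this depth for genes above a few CPM, and the spread between libraries (biological coefficient of variation 0.37) sets the precision. That spread holds differences between animals, dissection and library preparation, which cannot be told apart here.

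Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM normalization, filterByExpr by group, quasi-likelihood fit and test, 1 model with a mean per group over all 15 libraries, 12 residual degrees of freedom). After filtering 14194 genes were tested. Adjustment was by Benjamini-Hochberg per comparison, with 0.05 as the threshold. Levels are in edgeR's CPM unit, on TMM-scaled library sizes, and log2 CPM uses a prior count of 2. Gene positions came from GENCODE M21, which holds 14215 of the identifiers. The comparisons were crush against sham with AAV-null, AAV-CNTF against AAV-null after crush, and crush with AAV-CNTF against sham.

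Gene lists for cell types, pathways and possible contaminating tissues, the comparisons, the tests, the alternatives and the rule for naming genes were set before the data were examined. Each list of at least 3 tested genes was tested with camera (limma 3.58.1, preset correlation 0.01), beside camera with a correlation estimated per list and fry, adjusted over the lists. Some lists share genes, such as Gfap in the astrocyte, reactive astrocyte and STAT3 lists. The mean log2 CPM of each list per library was compared by an exact permutation test, two-sided, over all 252 assignments. By the rule, the genes named are the 5 with the largest change in each direction among those past the threshold with a mean of at least 5 CPM and no overlap between groups. They also are up to 2 genes past the threshold from each main list and 1 from each other list, the most abundant member where none passed, and Cntf, Socs3, Stat3, Gfap, Cspg4, Pdgfra and Olig2. With under 10 genes past the threshold, all of them and the 10 next by p are named. Some genes that the rule or a list count selects are not reported here. Where a list count was 5 or fewer, members named without a value were chosen after their values were seen.

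Alternatives were RLE and upper quartile normalization, no low-count filter, a mean of at least 1 CPM, mitochondrial, Rn* and the 10 most abundant genes left out, only the 10 libraries compared, replicate number as a block, the skeletal muscle list level as a covariate, and each library left out in turn. Other tests were limma-voom with sample quality weights and DESeq2 1.42.0. Leaving out crush AAV-null replicate 6 and crush AAV-CNTF replicate 4 together, list counts without single libraries that stand apart, splits of the 10 crush libraries fitted without sham, and DESeq2 with a fold of at least 1.5 were added after the data were seen. Replicate numbers were checked for pairing by the correlation of deviations from the group means, which was -0.05 to 0.11 over 15 same-number pairs. Of these, 3 were best with their own number, all between the crush groups (replicates 2, 3 and 5, at 0.11, 0.03 and 0.04). These values are low, and the libraries were not treated as paired in the main model. No 2 libraries of a group were duplicates (chi-square per degree of freedom 40.69 to 153.83 over 30 pairs). Xist was at 1134 to 1489 CPM in each library and no Y-linked gene is listed, so a sex covariate was not run. The test was checked on simulated counts in 5 runs with changed genes, in which 15 of 554 calls were false. Fastq files, splicing and the authors' FPKM values beyond their minimum were not analysed here. Reads shared between paralogs, such as H2-Q6 and H2-Q7 or the histone genes, were divided by RSEM, and that division was not tested.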

Results

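RNA was measured in optic nerves of adult C57BL/6J mice whose eyes had been injected with an adeno-associated virus (AAV, a gene delivery vector). The optic nerve carries the axons of retinal ganglion cells, whose cell bodies lie in the retina, and its own cells are mainly oligodendrocytes, astrocytes, NG2 glia (oligodendrocyte precursors), microglia and cells of the vessels and sheath. One virus, AAV-CNTF, carried a secreted form of ciliary neurotrophic factor, a cytokine that signals through the Il6st receptor subunit and STAT3, and the other, AAV-null, served as the control vector. The nerve was crushed 2 weeks after injection and collected 7 days after crush, or only exposed in the sham operation, for which the sample labels give no times. There were 3 groups of 5 biological replicates, numbered 2 to 6 in each: sham with AAV-null, crush with AAV-null and crush with AAV-CNTF. The listed genes held 19856688 to 26411929 expected counts per sham library, 19918858 to 29138927 per crush AAV-null library and 23775487 to 29558293 per crush AAV-CNTF library.

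The injury separated the libraries more than the virus did. Principal component 1 of log2 CPM (CPM, counts scaled to a common library size) held 33.5% of the variance and placed the 5 sham libraries at 54.8 to 87 and the 10 crush libraries at -47.2 to -20.3. Component 2 held 8.9% and set apart crush AAV-null replicate 6, at -99.7, while the other 14 libraries lay between -9 and 24. That library had 3.18% of the listed genes at a count of 0, against 0.98% to 2.32% in the others. Its total of 29138927 counts was the highest of its group.

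**Figure D1:**
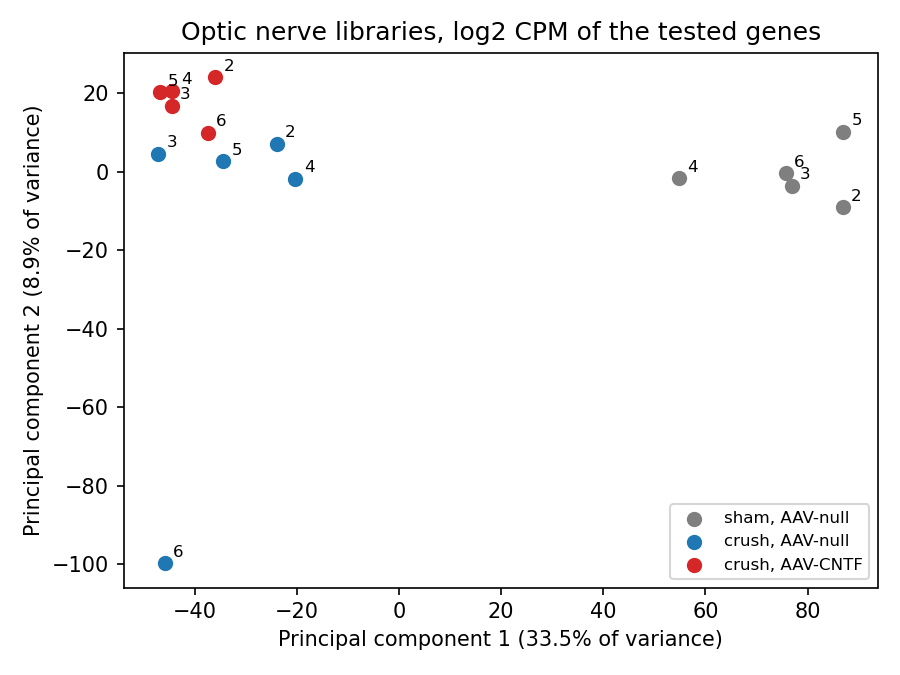
Principal components 1 and 2 of log2 CPM, 1 point per library, labelled with its replicate number and coloured by group. Sham libraries sit at 54.8 or above on component 1, crush libraries at -20.3 or below, and crush AAV-null replicate 6 lies at -99.7 on component 2.

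The first comparison, crush against sham with AAV-null in both, asks what a crush injury does to the transcripts of the nerve. In crushed nerves, transcripts of phagocytes and dividing cells rose, and transcripts of myelin, cholesterol synthesis and several axonal proteins fell. Mki67, a marker of proliferating cells, went from 13.3 ± 4.2 to 177 ± 31.1 CPM (SD, n = 5 each), and Ctsd, a lysosomal protease, from 623 ± 136 to 5810 ± 996 CPM. Unc13c, a presynaptic protein gene, went from 2759 ± 658 to 44.1 ± 14.3 CPM. Of 14194 genes tested, 2087 were higher and 1825 lower after crush by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1000 and 493 of them by at least 2-fold. At an unadjusted p under 0.05 there were 5260 genes, where 710 would be expected by chance.

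The 5 largest falls by the naming rule were in Pcp4, Unc13c, Sptbn4, Calb2 and Rph3a. Sptbn4 encodes a spectrin of the axon initial segment and nodes of Ranvier, and Calb2 (calretinin) and Pcp4 encode calcium-binding and calmodulin-binding proteins of neurons. Unc13c (chromosome 9, 73479422 to 73968966, mm10) had a log2 fold change of -5.97 ± 0.27 (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 8.9e-12). Sptbn4 changed by -5.96 ± 0.36 and Rph3a, a synaptic vesicle protein gene, by -5.58 ± 0.33 (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 3.56e-10 for both). Calb2 went from 8.46 ± 2.56 to 0.146 ± 0.233 CPM (SD, n = 5 each). Pcp4 had no count in any crush AAV-null library and 7.14 CPM in sham, a level at least 281-fold lower when 3 counts over the group are taken as the floor. In the list of retinal ganglion cell and axon transcripts, 3 of 11 tested members rose (Stmn2, Thy1 and Gap43), 4 fell (Nefh, Snap25, Nefl and Nefm) and 4 passed in neither direction. Adjusted over the list alone the counts were 3 and 5. Nefh, the heavy neurofilament subunit, went from 82.0 ± 8.38 to 1.77 ± 1.47 CPM (SD, n = 5 each). The list did not pass camera, a test of a list against all other genes (Benjamini-Hochberg adjusted p = 0.251), and its median log2 fold change was -0.26. Its mean level per library fell from 4.28 ± 0.12 to 2.68 ± 0.35 log2 CPM (SD, n = 5 each). The exact permutation p, two-sided, was 0.00794 (0.0149 after Benjamini-Hochberg adjustment over the lists). It also passed fry (fry adjusted p = 0.00373), which asks another question than camera.

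Myelin, cholesterol synthesis and mitochondrial genes fell as groups. Of 20 mature oligodendrocyte and myelin genes, 19 fell and none rose (19 adjusted over the list alone), with a median log2 fold change of -1.01 (camera adjusted p = 1.5e-14; adjusted p = 0.108 with an estimated correlation). Mal, a myelin proteolipid, fell by 1.56 on the log2 scale, from 1111 ± 164 to 376 ± 44.2 CPM, and Mobp fell by 1.55, from 7525 ± 811 to 2570 ± 434 CPM (SD, n = 5 each). Of 18 cholesterol synthesis genes, 16 fell (17 adjusted over the list alone), with a median of -1.08 (camera adjusted p = 7.11e-11; adjusted p = 0.107 with an estimated correlation). Hmgcs1, the enzyme ahead of HMG-CoA reductase, went from 416 ± 73.2 to 166 ± 25.7 CPM (SD, n = 5 each). All 9 mitochondrially encoded mRNAs in the list fell (9 adjusted over the list alone), with a median of -0.91 (camera adjusted p = 1.78e-06; adjusted p = 0.108 with an estimated correlation). mt-Nd1, a complex I subunit, went from 11540 ± 688 to 4504 ± 489 CPM (SD, n = 5 each).

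Phagocyte and microglial transcripts moved the other way. Of 23 phagocyte and macrophage genes, 21 rose (21 adjusted over the list alone), with a median log2 fold change of 2.35 (camera adjusted p = 3.16e-18; adjusted p = 0.0317 with an estimated correlation). Ctsd rose by 3.22 ± 0.18 and Lpl, lipoprotein lipase, by 3.40 ± 0.21 on the log2 scale (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.56e-10 and 4.98e-10). Of 12 homeostatic microglia genes, 9 rose and 1, Sall1, fell (9 and 1 adjusted over the list alone; camera adjusted p = 1.98e-05; adjusted p = 0.108 with an estimated correlation). Fcrls went from 20.7 ± 9.48 to 238 ± 58.2 CPM and Olfml3 from 100 ± 16.6 to 278 ± 24.7 CPM (SD, n = 5 each). In the complement list 7 of 16 genes rose and 2, C3 and C4b, fell (7 and 2 adjusted over the list alone; camera adjusted p = 9.59e-05; adjusted p = 0.118 with an estimated correlation). C3ar1, the C3a receptor, was 7.23 times higher. Of 17 chemokines 6 rose (6 adjusted over the list alone; camera adjusted p = 0.0113; adjusted p = 0.192 with an estimated correlation), Ccl6 from 13.1 ± 3.90 to 53.9 ± 13.4 CPM (SD, n = 5 each). Adam8, a metalloprotease of myeloid cells, went from 0.620 ± 0.392 to 35.5 ± 24.6 CPM (SD, n = 5 each) and was among the 5 largest rises by the naming rule, with Kif2c, Kif18b, Stra6l and Tgm1.

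Cell division genes rose almost without exception. In the cell cycle list 19 of 20 genes rose and 1 passed in neither direction (19 adjusted over the list alone), with a median log2 fold change of 3.13 (camera adjusted p = 1.32e-12; adjusted p = 0.0317 with an estimated correlation). Top2a, the DNA topoisomerase of dividing cells, went from 3.92 ± 2.03 to 73.0 ± 8.14 CPM (SD, n = 5 each). Kif2c, a mitotic kinesin, had no count in any sham library and 6.68 CPM after crush, at least 238-fold higher against 3 counts over the group. Stra6l, related to a retinol transporter gene, likewise had none in sham and 8.39 CPM after crush, at least 299-fold higher. Kif18b, another mitotic kinesin, rose from 0.111 ± 0.248 to 12.6 ± 2.49 CPM, and Tgm1, a transglutaminase, from 0.130 ± 0.162 to 7.55 ± 3.99 CPM (SD, n = 5 each).

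Astrocyte transcripts fell while most genes of the reactive astrocyte list rose or did not pass. Of 16 astrocyte genes 13 fell and none rose (13 adjusted over the list alone), with a median log2 fold change of -0.47 (camera adjusted p = 8.6e-06; adjusted p = 0.108 with an estimated correlation). Gfap, the astrocyte intermediate filament, went from 4299 ± 238 to 3092 ± 399 CPM, Ndrg2 from 308 ± 14.9 to 177 ± 17.0 CPM and S100b from 612 ± 39.2 to 346 ± 64.6 CPM (SD, n = 5 each). Of 21 reactive astrocyte genes 12 rose and 1, Gfap, fell (13 and 1 adjusted over the list alone; camera adjusted p = 0.000882; adjusted p = 0.118 with an estimated correlation). Timp1, an inhibitor of matrix proteases, went from 12.1 ± 2.29 to 74.6 ± 6.80 CPM, and Cd14, which myeloid cells also express, from 9.11 ± 2.24 to 31.7 ± 4.34 CPM (SD, n = 5 each). Of 17 genes of BMP, Notch and NFI signalling in astrocyte differentiation, 5 fell (Id4, Bmpr1b, Sox9, Nfia and Id2) and none rose (7 lower and 2 higher adjusted over the list alone), and the list did not pass camera (adjusted p = 0.0861). Its mean level per library was lower by 0.21 log2 CPM (exact permutation p = 0.0317, two-sided, 0.0475 after adjustment), and it passed fry (fry adjusted p = 0.000685). Id4 went from 210 ± 26.3 to 94.1 ± 15.7 CPM (SD, n = 5 each).

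**Figure D2:**
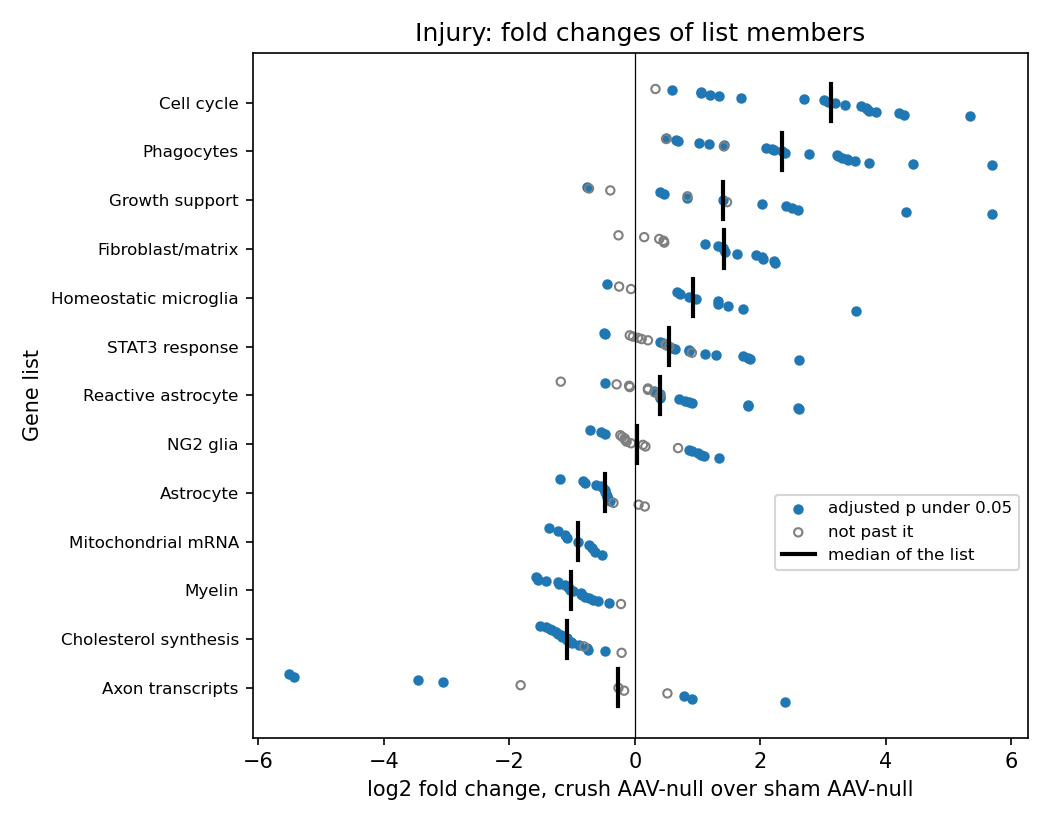
Log2 fold changes of crush over sham, both with AAV-null, for each tested member of 13 gene lists. Filled points passed an adjusted p of 0.05, open points did not, and bars are list medians, which run from 3.13 for the cell cycle to -1.08 for cholesterol synthesis.

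NG2 glia genes went both ways. Of 18 members 6 rose and 3 (Olig1, Olig2 and Sox10) fell (7 and 3 adjusted over the list alone), the median log2 fold change was 0.03, and the list did not pass camera (adjusted p = 0.271). It did not pass fry either (fry adjusted p = 0.0643). Its mean level per library was higher after crush, at 6.2 ± 0.06 log2 CPM in sham and 6.45 ± 0.13 in crush (SD, n = 5 each). The exact permutation p, two-sided, was 0.0159 (0.0251 after adjustment). Cspg4, which encodes the NG2 proteoglycan, rose from 64.3 ± 7.86 to 164 ± 23.2 CPM (SD, n = 5 each; log2 fold change 1.35 ± 0.13 SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.77e-07). Vcan, the proteoglycan versican, rose 1.99-fold. Pdgfra, the receptor that marks the same cells, was at 131 ± 15.1 CPM in sham and 118 ± 12.7 CPM after crush and did not pass, and Olig2 went from 150 ± 17.9 to 103 ± 13.2 CPM (SD, n = 5 each).

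STAT3 and cytokine response genes rose in part. Of 23 members 12 rose and 2, Il6st and Gfap, fell (15 and 2 adjusted over the list alone; camera adjusted p = 0.000383; adjusted p = 0.118 with an estimated correlation). Socs3, a feedback inhibitor of this pathway, went from 21.4 ± 3.60 to 52.3 ± 14.9 CPM and Myc from 11.7 ± 1.73 to 38.9 ± 9.94 CPM (SD, n = 5 each). Stat3 was at 193 ± 6.70 and 182 ± 14.6 CPM and did not pass (SD, n = 5 each). Of 15 tested genes for cytokines of the CNTF family, their receptors and kinases, 4 rose (Jak1, Il6ra and Osmr among them) and 5 fell (Lifr, Cntfr, Il6st, Jak2 and Cntf), or 6 and 5 adjusted over the list alone. The list did not pass camera (adjusted p = 0.913). Cntf itself went from 16.4 ± 5.04 to 5.29 ± 3.24 CPM, its receptor Cntfr from 123 ± 15.6 to 59.2 ± 15.8 CPM and Lifr from 122 ± 12.9 to 75.3 ± 7.29 CPM (SD, n = 5 each).

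Most genes of the fibroblast and matrix list and of the axon growth support list rose. Of 16 fibroblast and matrix genes 11 rose (13 adjusted over the list alone), with a median log2 fold change of 1.41 (camera adjusted p = 1.48e-06; adjusted p = 0.261 with an estimated correlation). Col1a1 went from 616 ± 222 to 2357 ± 526 CPM and Lox, which cross-links collagen, from 30.2 ± 11.97 to 141 ± 36.3 CPM (SD, n = 5 each). Of 15 tested genes for factors that support axon growth 10 rose and 1, Lama1, fell (12 and 2 adjusted over the list alone; camera adjusted p = 0.000102; adjusted p = 0.118 with an estimated correlation). Igf1, a growth factor, went from 8.38 ± 4.44 to 167 ± 51.0 CPM (SD, n = 5 each). Of 18 genes for inhibitors of axon growth 4 rose (Cspg4, Ncan, Vcan and Tnr) and 7 fell (5 and 7 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.37).

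Among antigen presentation genes, 3 of 7 MHC class II genes rose (H2-DMa, H2-DMb1 and H2-Aa; 4 adjusted over the list alone; camera adjusted p = 0.0216; adjusted p = 0.459 with an estimated correlation and 0.0663 on limma-voom values) and H2-DMa was 2.4 times higher. Of 11 MHC class I genes 2 rose, Tapbp and B2m (2 adjusted over the list alone), while of 19 interferon response genes 3 fell, Ifit1, Ifit2 and Ifit3 (3 adjusted over the list alone). Neither list passed camera (adjusted p = 0.187 and 0.256). Tapbp, the chaperone of peptide loading, went from 106 ± 10.8 to 144 ± 14.5 CPM and Ifit2 from 55.0 ± 12.5 to 28.2 ± 1.92 CPM (SD, n = 5 each). Tapbp lost its call without sham replicate 6, with a log2 fold change of 0.38 against 0.44.

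Markers of other cells were measured beside these groups. Of 13 genes of the neutrophil list only 3 were among the listed genes, so the list says little about these cells. Of the 3 genes 2 rose, Csf3r and Retnlg (2 adjusted over the list alone), Csf3r from 29.3 ± 3.96 to 68.5 ± 10.1 CPM (SD, n = 5 each). Of 8 T and NK cell genes 1, Lck, fell, with 155 counts over the sham libraries and 8 over crush AAV-null (1 adjusted over the list alone). Of 4 B and plasma cell genes 2, Igkc and Jchain, fell (2 adjusted over the list alone), Igkc from 344 ± 89.3 to 108 ± 47.5 CPM (SD, n = 5 each). Of 13 endothelial genes 1 rose (Cdh5) and 3 fell (Slc2a1, Flt1 and Egfl7), or 1 and 4 adjusted over the list alone. Slc2a1, the glucose transporter of brain endothelium, went from 212 ± 11.7 to 131 ± 11.3 CPM (SD, n = 5 each). Of 11 pericyte and smooth muscle genes 4 rose (Anpep, Tagln, Acta2 and Cnn1) and 2 fell, Kcnj8 and Vtn (6 and 2 adjusted over the list alone), Anpep from 50.7 ± 12.9 to 167 ± 32.3 CPM (SD, n = 5 each). Of 5 Schwann cell genes 1, Cdh19, fell, from 63.5 ± 9.06 to 34.5 ± 7.21 CPM (SD, n = 5 each), and 1 rose and 1 fell adjusted over the list alone. None of the 8 skeletal muscle genes passed, and their mean level varied widely, at 2.35 ± 1.15 log2 CPM in sham and 0.55 ± 1.41 after crush (SD, n = 5 each). Atp2a1, a calcium pump of muscle, was at 28.1 ± 39.6 and 7.46 ± 8.01 CPM (SD, n = 5 each), and passed without crush AAV-null replicate 4 or sham replicate 4 (log2 fold changes -2.83 and -2.2). Of 12 genes of the early stress response to dissection 3 rose (Atf3, Egr1 and Fos) and 1, Dusp1, fell (5 and 2 adjusted over the list alone), Atf3 from 9.64 ± 3.02 to 27.4 ± 6.43 CPM (SD, n = 5 each). None of these 8 cell type and stress lists passed camera (adjusted p from 0.0767 to 0.793). By mean level per library, the T and NK list (-1.27 log2 CPM) and the B and plasma cell list (-1.34) were lower. The pericyte and smooth muscle list was higher (0.44). Their exact permutation p, two-sided and adjusted over the lists, was 0.0251, 0.0251 and 0.0149, against 0.0907 to 0.817 for the others. By fry the neutrophil, T and NK, B and plasma cell and stress lists passed (fry adjusted p = 0.000329, 0.0193, 0.021 and 0.0372). Few members were tested of the retina (1 gene), pigment epithelium (1), adipocyte (1) and red blood cell (2) lists. The adipocyte gene, Lipe, fell from 19.8 ± 2.25 to 12.9 ± 4.02 CPM (SD, n = 5 each; log2 fold change -0.62). This call was lost with the skeletal muscle covariate (-0.51) or without sham replicate 3 (-0.55) or crush AAV-null replicate 2 (-0.57), 3 (-0.56), 5 (-0.58) or 6 (-0.56). Rom1 of photoreceptors was at 10.8 ± 2.86 and 9.31 ± 2.54 CPM, Rlbp1 of pigment epithelium at 16.9 ± 5.30 and 9.96 ± 3.62 CPM and Hba-a2, an alpha globin, at 4.28 ± 2.26 and 1.40 ± 1.22 CPM (SD, n = 5 each). The 4 genes of these lists other than Lipe did not pass. Adjusted over the list alone Rlbp1 and Lipe were lower. Rlbp1 also passed without crush AAV-CNTF replicate 6 (-0.77), crush AAV-null replicate 3 (-0.92) or 4 (-0.9) or sham replicate 3 (-0.91).

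The second comparison, AAV-CNTF against AAV-null in crushed nerves, addresses what the AAV-CNTF vector adds after injury. The groups differ in their vector, so CNTF signalling cannot be told apart from another response to the vector or its product. No sham group received AAV-CNTF. As lists, genes of the STAT3 response and of T and NK cells lay higher with CNTF. Antigen presentation and interferon genes did so by camera under the preset correlation, not an estimated one (camera adjusted p = 0.0876 for MHC class I, 0.0951 for class II and 0.202 for interferon). By fry, which asks another question, MHC class I and II passed (fry adjusted p = 0.0191 and 0.027) and interferon did not (0.0951). The genes for the astrocyte marker Gfap and the NG2 glia markers Cspg4, Pdgfra and Olig2 did not pass in either direction. Plvap, a protein of fenestrated and permeable endothelium, rose 2.89-fold, from 18.6 ± 4.62 to 53.7 ± 16.6 CPM, and the MHC class I gene H2-Q7 rose 6.63-fold, from 9.53 ± 4.16 to 63.1 ± 52.8 CPM (SD, n = 5 each). Crush AAV-CNTF replicate 4 held 155 CPM of H2-Q7, against 26.1 to 58.9 in the other 4, and without it the log2 fold change was 2.07 in place of 2.73 and did not pass. Fyn, a Src family kinase of oligodendrocytes, neurons and T cells, fell 1.44-fold, from 161 ± 8.29 to 111 ± 10.2 CPM (SD, n = 5 each). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 6 genes were higher and 2 lower among 14194. At an unadjusted p under 0.05 there were 1091 genes, where 710 would be expected by chance, but 3 of 99 other groupings of the 10 crush libraries gave more (1111, 1123 and 1319). At an adjusted p under 0.1 there were 38. DESeq2 on the same counts called 59 higher and 24 lower, which included these 8, and the authors' deposited table holds 79 genes with an adjusted p under 0.05, 59 higher and 20 lower, which also included the 8 with the same sign. Other settings gave more or fewer: 15 higher and 8 lower with the skeletal muscle covariate, 14 and 2 with replicate as a block, 1 and 0 with only the 10 crush libraries in the model, 3 and 2 with limma-voom, and 2 and 0 without both crush AAV-null replicate 6 and crush AAV-CNTF replicate 4.

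The 8 genes lie apart in the genome except for those of the MHC region. Plvap (chromosome 8, 71497765 to 71511752, mm10) changed by 1.53 ± 0.22, H2-Q7 (chromosome 17, 35439155 to 35443773) by 2.73 ± 0.45 and Cxcl9 (chromosome 5, 92321347 to 92328079), a chemokine induced by interferon gamma, by 7.42 ± 1.31 on the log2 scale (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0127, 0.0261 and 0.0368). Rhoj (chromosome 12, 75308322 to 75401456), an endothelial small GTPase, changed by 0.65 ± 0.11, H2-Eb1 (chromosome 17, 34305867 to 34316674), an MHC class II chain, by 1.75 ± 0.32, and Cd74 (chromosome 18, 60803848 to 60812652), the invariant chain, by 2.22 ± 0.41 (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0368, 0.0473 and 0.0473). Fyn (chromosome 10, 39368855 to 39565381) changed by -0.53 ± 0.09 and Tmem132b (chromosome 5, 125531774 to 125792583), a membrane protein gene, by -0.85 ± 0.14 (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0261 for both). In Plvap, H2-Q7, Rhoj, Fyn and Tmem132b the 5 and 5 libraries did not overlap. Cxcl9 was uneven, at 648 CPM in crush AAV-CNTF replicate 4 and 1.6 to 70 CPM in the other 4, against a mean of 0.956 CPM with AAV-null. Without that library the log2 fold changes were 5.23 for Cxcl9, 1.54 for Cd74 and 1.37 for H2-Eb1, and none of the 3 passed. H2-Q7 has near-identical neighbours such as H2-Q6, so the division of reads between them is uncertain.

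**Figure D3:**
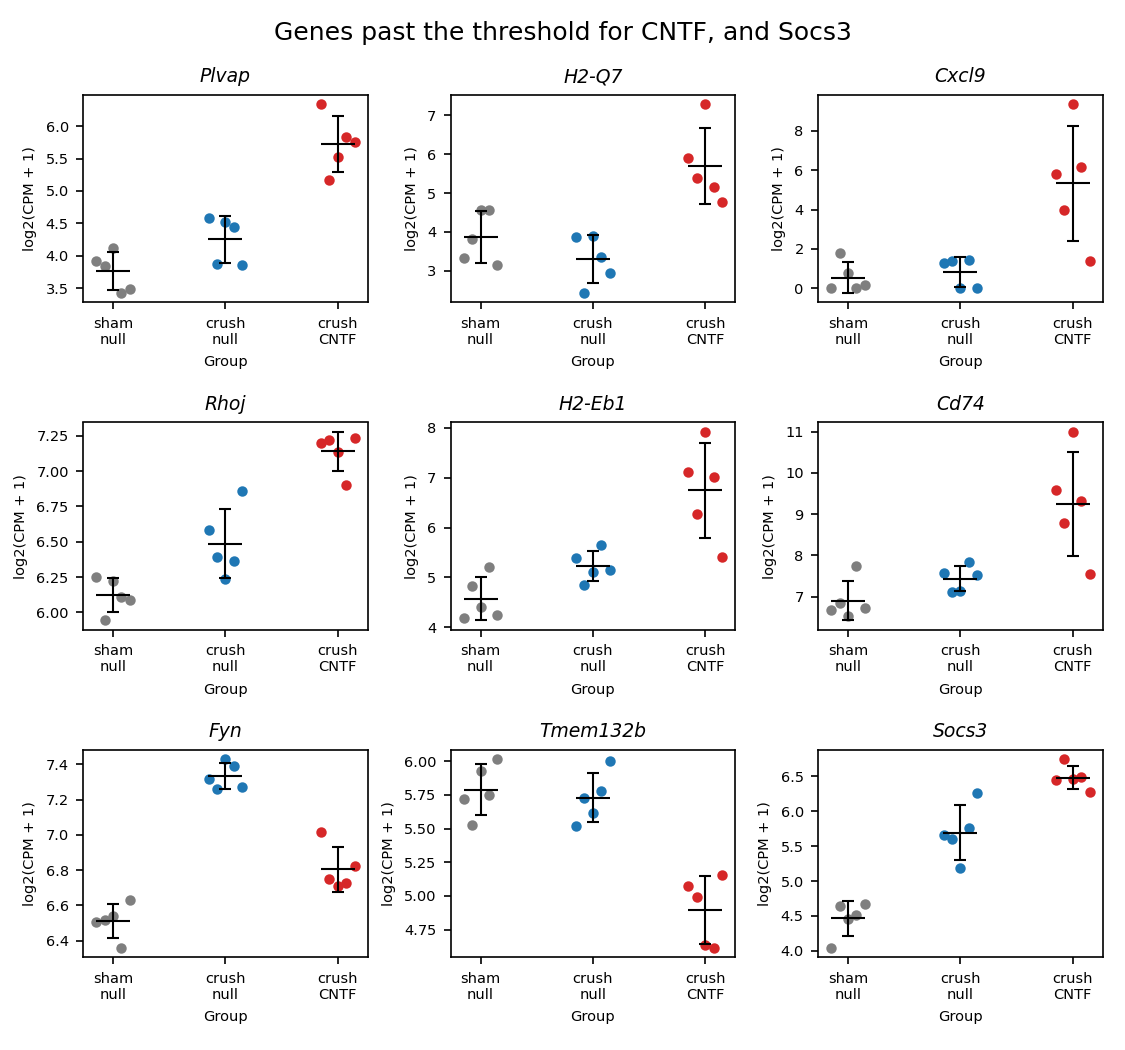
Level per library, as log2(CPM + 1), of the 8 genes past the threshold for AAV-CNTF against AAV-null after crush, and of Socs3. Points are libraries and bars mark the mean ± SD of 5; Cxcl9 ranges from 1.6 to 648 CPM across the crush AAV-CNTF libraries.

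The count of 8 depended on single libraries. Without crush AAV-CNTF replicate 6 there were 38 higher and 3 lower genes, and without crush AAV-CNTF replicate 4 there were 1 and 1. Plvap passed in each of the 26 alternative settings and single-library omissions (highest edgeR, voom or DESeq2 adjusted p, Benjamini-Hochberg, 0.0492), and each of the other 7 genes lost its call in at least 6 of them. Leaving out another library gave 3 and 3 (AAV-CNTF 2), 14 and 2 (AAV-CNTF 3), and 10 and 2 (AAV-CNTF 5). For AAV-null the counts were 1 and 0 (AAV-null 2), 1 and 2 (AAV-null 3), 1 and 0 (AAV-null 4), 2 and 0 (AAV-null 5) and 3 and 1 (AAV-null 6). For sham they were 2 and 2 (2), 4 and 2 (3), 2 and 2 (4), 8 and 2 (5) and 3 and 2 (6). In simulated counts with the spread of these libraries, the same test for this comparison recovered 23% of genes changed 1.5-fold, 54.9% of those changed 2-fold and 84.2% of those changed 4-fold, over 14154 genes. Each simulation changed 200 genes above a minimum count and drew the genes independently, with no outlying library. Recovery depends on these settings, so it may differ in the real libraries.

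The 10 genes next in order did not pass by edgeR, while DESeq2 with a fold of at least 1.5 called all 10. They were H2-Aa, C3, Lck, H2-Ab1, H2-Q6, Unc13c, Fgl2, Mgst1, H2-Q4 and H2-K1, with edgeR quasi-likelihood, Benjamini-Hochberg adjusted p between 0.0506 and 0.0645. H2-Aa was at 37.8 ± 3.18 CPM with AAV-null and 124 ± 75.8 CPM with AAV-CNTF, H2-Ab1 at 55.0 ± 17.0 and 209 ± 162 CPM (SD, n = 5 each). H2-K1 was at 217 ± 35.3 and 464 ± 209 CPM, H2-Q4 at 30.4 ± 7.12 and 97.2 ± 69.9 CPM and H2-Q6 at 5.03 ± 1.24 and 24.99 ± 25.7 CPM (SD, n = 5 each). Without crush AAV-CNTF replicate 4 the log2 fold change fell from 2.32 to 1.44 for H2-Q6, from 1.93 to 1.37 for H2-Ab1 and from 1.68 to 1.15 for H2-Q4. C3 was at 207 ± 45.7 and 422 ± 166 CPM, Fgl2, a secreted immune regulator, at 52.8 ± 4.63 and 97.7 ± 36.3 CPM, and Mgst1, a glutathione transferase, at 19.5 ± 3.71 and 33.3 ± 5.39 CPM (SD, n = 5 each). Unc13c was at 44.1 ± 14.3 and 19.9 ± 6.66 CPM, and the T cell kinase Lck had 8 counts over the 5 AAV-null libraries and 576 over the 5 AAV-CNTF libraries. Socs3 was at 52.3 ± 14.9 CPM with AAV-null and 88.9 ± 10.7 CPM with AAV-CNTF (SD, n = 5 each), a log2 fold change of 0.76 ± 0.17 (SE). It did not pass by edgeR (quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0788), although its 5 and 5 values did not overlap. DESeq2 with that fold also called Socs3.

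As lists, STAT3 response and T and NK cell genes were higher with CNTF under each form of the camera test. The STAT3 and cytokine response list had 22 of 23 members with a positive fold change and a median of 0.41. By edgeR 0 members passed over all genes and 10 adjusted over the list alone (camera adjusted p = 1.55e-10, or 0.0268 with an estimated correlation). DESeq2 with a fold of at least 1.5 called Socs3, Irf1 and Fos of this list. The mean level of the list was 5.42 ± 0.07 log2 CPM with AAV-null and 5.95 ± 0.24 with AAV-CNTF (SD, n = 5 each). It was higher in 5 of 5 AAV-CNTF libraries than in every AAV-null library (exact permutation p = 0.00794, two-sided, the smallest that 5 against 5 can give; 0.0794 after Benjamini-Hochberg adjustment over the lists). Stat3 was at 182 ± 14.6 and 219 ± 17.3 CPM, and Gfap, the most abundant member, at 3092 ± 399 and 3093 ± 254 CPM (SD, n = 5 each). Of 15 T and NK cell genes 8 were among the listed genes, and all 8 had a positive fold change, with a median of 1.94. By edgeR none passed over all genes and 5 adjusted over the list alone (camera adjusted p = 1.42e-09, or 0.0268 with an estimated correlation). DESeq2 with a fold of at least 1.5 called Lck. Listed genes have an FPKM of at least 1 in at least 4 libraries of some group. Genes this low can enter through the group where they are high, which can favour a shared sign. Cd4 was at 3.94 ± 0.946 and 10.9 ± 6.55 CPM, and the list level at -0.30 ± 0.81 and 2.04 ± 0.86 log2 CPM, against 0.97 ± 0.71 in sham (SD, n = 5 each). These are low levels, near 1 to 10 CPM, and the list was higher in 5 of 5 AAV-CNTF libraries than in every AAV-null library (exact permutation p = 0.00794, two-sided; 0.0794 after adjustment).

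Antigen presentation and interferon lists were also higher by camera, but not with an estimated correlation. For MHC class I all 11 members had a positive fold change, with a median of 0.97. By edgeR 0 passed over all genes and 11 adjusted over the list alone (camera adjusted p = 1.08e-12, or 0.0876 with an estimated correlation). DESeq2 with a fold of at least 1.5 called H2-K1, H2-D1, H2-Q4 and Tap1. B2m was at 1331 ± 107 and 2468 ± 1226 CPM (SD, n = 5 each). For MHC class II 2 of 7 rose by edgeR, H2-Eb1 and Cd74, and 7 adjusted over the list alone (median 1.75, camera adjusted p = 9e-10, or 0.0951 with an estimated correlation). At this fold DESeq2 called these and H2-Aa, H2-Ab1 and Ciita. For the interferon response all 19 were positive, and by edgeR 0 passed over all genes and 10 adjusted over the list alone (median 0.86, camera adjusted p = 1.01e-10, or 0.202 with an estimated correlation). Of this list DESeq2 with that fold called Gbp2. Gbp2, a guanylate-binding GTPase, was at 42.4 ± 5.05 and 182 ± 217 CPM (SD, n = 5 each), and its log2 fold change fell from 2.1 to 1.02 without crush AAV-CNTF replicate 4, which held 566.9 CPM. For chemokines 1 of 17, Cxcl9, rose, and 6 adjusted over the list alone (median 0.64; camera adjusted p = 7.68e-06; adjusted p = 0.0635 with an estimated correlation). Crush AAV-CNTF replicate 4 was the highest library of its group for all 4 of these lists, at 7.70 log2 CPM for MHC class I, 7.58 for class II, 5.74 for interferon and 4.69 for chemokines. AAV-CNTF replicate 6 was the lowest, at 6.23, 4.92, 4.16 and 2.86. The exact permutation p of these list levels, two-sided, was 0.00794, 0.0238, 0.0238 and 0.0159, and 0.0794 to 0.102 after adjustment. Sham replicate 3, at 5.13, was above 4 of the 5 AAV-CNTF libraries for the interferon list.

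**Figure D4:**
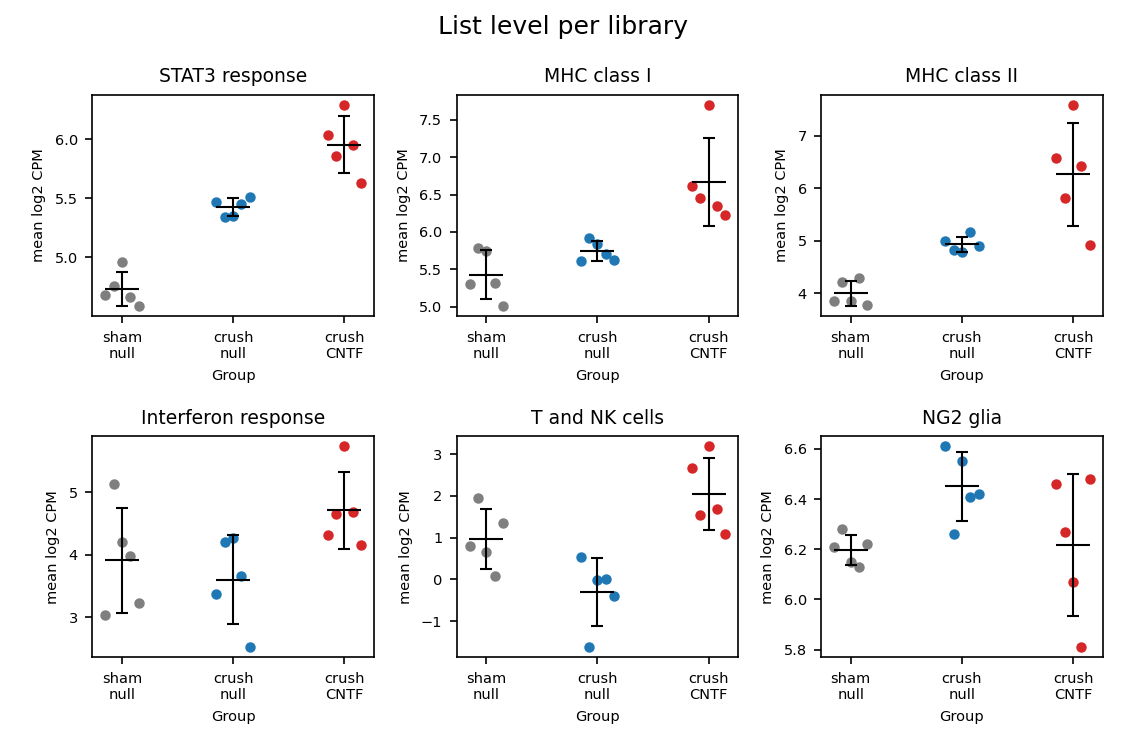
Mean log2 CPM of the members of 6 gene lists in each library, with the mean ± SD of 5 libraries per group. The STAT3, MHC class I and T and NK cell lists are higher in each of the 5 crush AAV-CNTF libraries than in every crush AAV-null library, and the NG2 glia list overlaps between them.

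Glial lists shifted by small amounts with CNTF, with no member past edgeR's threshold over all genes. DESeq2 with a fold of at least 1.5 called Gpnmb of the phagocyte list. The NG2 glia list was lower, with 2 of 18 members positive and a median log2 fold change of -0.16 (0 adjusted over the list alone; camera adjusted p = 0.000157; adjusted p = 0.29 with an estimated correlation). Cspg4 was at 164 ± 23.2 CPM with AAV-null and 122 ± 22.9 with AAV-CNTF, Pdgfra at 118 ± 12.7 and 111 ± 3.61 CPM (SD, n = 5 each). Olig2 was at 103 ± 13.2 and 101 ± 22.1, and Tnr, the most abundant member, at 597 ± 69.4 and 509 ± 141 CPM (SD, n = 5 each). The myelin list was lower (median -0.17; 1 adjusted over the list alone; camera adjusted p = 0.00231; adjusted p = 0.518 with an estimated correlation), Mbp at 13050 ± 2229 and 11130 ± 1898 CPM (SD, n = 5 each). So was the cholesterol list (median -0.19; 0 adjusted over the list alone; camera adjusted p = 0.00638; adjusted p = 0.443 with an estimated correlation), Hmgcs1 at 166 ± 25.7 and 133 ± 21.4 CPM (SD, n = 5 each). The phagocyte list was lower (median -0.22; 2 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.0193; adjusted p = 0.518 with an estimated correlation), Apoe at 13110 ± 1030 and 11280 ± 2644 CPM (SD, n = 5 each). The list of growth inhibitors was lower as well (median -0.1; 0 adjusted over the list alone; camera adjusted p = 0.045; adjusted p = 0.518 with an estimated correlation), Mag at 941 ± 108 and 888 ± 152 CPM (SD, n = 5 each). Over 25 alternatives the NG2 glia call held in 25, cholesterol in 24, myelin in 23, phagocytes in 20 and growth inhibitors in 14. The highest camera adjusted p came without crush AAV-CNTF replicate 5 for myelin, cholesterol and growth inhibitors (0.147, 0.14 and 0.362) and without crush AAV-null replicate 3 for phagocytes (0.198). Without crush AAV-CNTF replicate 4 the phagocyte and growth inhibitor calls were also lost (0.0586 and 0.0609), and growth inhibitors without crush AAV-null replicate 6 (0.141). By the levels per library none of the 5 lower lists differed detectably (exact permutation p, two-sided, 0.143 for NG2 glia, 0.19 for myelin, 0.0714 for cholesterol, 0.595 for phagocytes and 0.103 for growth inhibitors). The astrocyte list did not pass (median -0.02; 0 adjusted over the list alone; camera adjusted p = 0.308). Homeostatic microglia did not pass either (median -0.1; 0 adjusted over the list alone; camera adjusted p = 0.0877).

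Other lists were higher by camera but not with an estimated correlation. The reactive astrocyte list had a median log2 fold change of 0.1 (2 adjusted over the list alone; camera adjusted p = 0.0175; adjusted p = 0.29 with an estimated correlation), Vim at 3871 ± 353 and 3923 ± 304 CPM (SD, n = 5 each). The CNTF family and receptor list had a median of 0.1 (1 adjusted over the list alone; camera adjusted p = 0.0138; adjusted p = 0.0951 with an estimated correlation). Il6st was at 409 ± 30.9 and 483 ± 64.8 CPM and Cntf mRNA, as counted for the mouse gene in the table, at 5.29 ± 3.24 and 5.64 ± 1.64 CPM (SD, n = 5 each). The fibroblast and matrix list had a median of 0.31 (0 adjusted over the list alone; camera adjusted p = 0.0135; adjusted p = 0.589 with an estimated correlation), Fn1 at 6056 ± 1996 and 5702 ± 1858 CPM (SD, n = 5 each). The complement list had a median of 0.22 (6 adjusted over the list alone; camera adjusted p = 0.0217; adjusted p = 0.407 with an estimated correlation), C4b at 1102 ± 133 and 1202 ± 96.2 CPM (SD, n = 5 each). Of 25 alternatives these calls held in 21 (reactive astrocyte), 23 (CNTF family), 21 (fibroblast) and 20 (complement). The highest camera adjusted p came without crush AAV-null replicate 3 (reactive astrocyte, 0.0966), AAV-null replicate 5 (CNTF family, 0.0666), AAV-CNTF replicate 5 (fibroblast, 0.303) and AAV-null replicate 4 (complement, 0.0988). Without AAV-CNTF replicate 4 the reactive astrocyte and complement calls were also lost (0.0609 and 0.0586). The exact permutation p of the list levels, two-sided, was 0.0317 for reactive astrocytes (0.119 after adjustment), 0.206 for the CNTF family, 0.365 for fibroblasts and 0.0556 for complement. The cell cycle list did not differ detectably (median -0.03; 0 adjusted over the list alone; camera adjusted p = 0.967), Mki67 at 177 ± 31.1 and 168 ± 33.6 CPM (SD, n = 5 each). None of the astrocyte differentiation, growth support, neutrophil, B and plasma cell, endothelial, pericyte, Schwann cell, axon, skeletal muscle, stress and mitochondrial lists passed camera (adjusted p from 0.0699 to 0.986) or had a member past edgeR's threshold. DESeq2 with a fold of at least 1.5 called Fos and Hspa1a of the stress list. Adjusted over the list alone, 1 endothelial gene, 1 stress gene and 1 mitochondrial gene were lower and 2 stress genes higher. Among the most abundant members, Nfia, a factor of glial differentiation, was at 445 ± 51.3 and 517 ± 41.4 CPM, Slc2a1 at 131 ± 11.3 and 104 ± 12.97 CPM (SD, n = 5 each). The level of Igkc was 108 ± 47.5 and 149 ± 100, that of Csf3r 68.5 ± 10.1 and 69.4 ± 9.39, and that of Tubb3, a neuronal tubulin, 65.1 ± 5.03 and 71.0 ± 23.7 CPM (SD, n = 5 each). Vtn, expressed by pericytes, was at 116 ± 27.0 and 123 ± 41.0, the myelin protein gene Pmp22 at 264 ± 19.4 and 280 ± 22.5, Jun at 212 ± 19.3 and 225 ± 15.9 and mt-Co1 at 12240 ± 811 and 12700 ± 1726 CPM (SD, n = 5 each). Atp2a1 was at 7.46 ± 8.01 and 6.12 ± 4.95, Lipe at 12.9 ± 4.02 and 13.3 ± 1.62, Rom1 at 9.31 ± 2.54 and 9.91 ± 3.15, Rlbp1 at 9.96 ± 3.62 and 10.8 ± 4.11 and Hba-a2 at 1.40 ± 1.22 and 2.19 ± 3.30 CPM (SD, n = 5 each). None of these 5 genes passed.

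The third pair, crush with AAV-CNTF against sham with AAV-null, combines injury and virus. It gave 2406 higher and 2031 lower genes (edgeR quasi-likelihood, Benjamini-Hochberg). Of 29 lists 16 passed camera, 11 higher and 5 lower, and 2 of them, phagocytes and the cell cycle, passed with an estimated correlation (adjusted p = 0.047 for both). The 5 lower lists include skeletal muscle, a possible contaminating tissue, with 3 of 8 genes lower (Myh1, Pvalb and Atp2a1; camera adjusted p = 0.038; past the threshold in 19 of 25 alternatives). Its level was 2.35 ± 1.15 log2 CPM in sham and 0.30 ± 1.52 in crush with AAV-CNTF (SD, n = 5 each), so a difference in muscle content between these groups is not ruled out. All 11 MHC class I genes and all 7 class II genes rose in this pair, and 18 of 23 STAT3 response genes rose and 2 fell. Of 19 interferon response genes 7 rose, and of 8 T and NK cell genes 1, Cd3e, and neither list passed camera (adjusted p = 0.0762 and 0.209). Without crush AAV-CNTF replicate 4, 4 interferon genes rose and 1 fell, and no T or NK cell gene passed. Without sham replicate 3, 8 and 2 rose and the interferon list passed camera (adjusted p = 0.00653). The authors deposited an adjusted p under 0.05 for 3786 genes for injury and for 4377 in this pair, of which edgeR also called 3610 and 4160, with the same sign in each.

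Across genes, the CNTF change was compared with the injury change to see whether CNTF moved transcripts along the direction of injury or against it. Both fold changes share the crush AAV-null libraries, with opposite signs, which makes their plain correlation negative by chance. It was -0.166 (Pearson, across 14194 genes, which are not independent replicates) and averaged -0.504 in 50 simulations with no effect of injury or virus. These values cannot be compared directly, since the injury changes, absent from the simulations, enlarge the real spread. When the 5 shared libraries were divided so that each contrast used its own, the mean correlation over 20 divisions was 0.031, from -0.076 to 0.155. The covariance was -0.0817 for the plain contrasts against -0.0869 (-0.0935 to -0.0784) in the simulations, a difference of 0.0051 that lies within their range. No relation in either direction was detectable.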

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

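The tests on 1 library alone, on splits with only the 10 crush libraries, on T and NK cells and on both explanations for crush AAV-CNTF replicate 6, and the T and NK cell condition added to the test of exchange with AAV-CNTF for crush AAV-null replicate 6, were chosen after the result was seen. A library was singled out when its gap to the nearest of the other 4 exceeded 0.71 of the range of its group. Chance does this in about 5% of groups, and 35 of 375 groups did so.

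In sham, replicate 3 had 11.81% of counts on Rn7s1 and Rn7s2 (others 5.11% to 6.94%), Cntfr at 95.2 CPM, Fgl2 at 93.7, Lipe at 23.8, Cxcl9 at 2.5 and Kif18b at 0.6 CPM. Sham replicate 5 had Atp2a1 at 98.5, Cd74 at 211.4 and Il6st at 515.9 CPM and an astrocyte list level of 8.52 log2 CPM. Sham replicate 4 had a homeostatic microglia level of 6.23 log2 CPM and H2-Q6 at 10.3 CPM, and sham replicate 2 had a mitochondrial level of 12.81 log2 CPM. In crush AAV-null, replicate 3 had a cell cycle level of 4.57 log2 CPM and C3ar1 at 195.6 CPM, replicate 4 had Atp2a1 at 21.5 and Lipe at 20.1 CPM, and replicate 5 had an axon list level of 3.3 log2 CPM and Lck at 0.4 CPM. Crush AAV-null replicate 6 had a total of 29138927 counts (29.1 M) and 3.18% of genes at 0. In crush AAV-CNTF, replicate 2 had Kif18b at 13.7 CPM, and replicate 5 had levels of 6.52 for homeostatic microglia and 5.36 for Schwann cells (log2 CPM) and Hba-a2 at 7.9 CPM. Crush AAV-CNTF replicate 4 had an MHC class I level of 7.7 log2 CPM, Cxcl9 at 648.4, Gbp2 at 566.9, Stat3 at 248.6, H2-Q7 at 155 and H2-Q6 at 70.5 CPM. Crush AAV-CNTF replicate 6 had 8.89% of counts on Rn7s1 and Rn7s2 (others 4.17% to 4.47%), Stra6l at 10.2, Pcp4 at 0.6 and Calb2 at 0.5 CPM.

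Immune genes were higher with AAV-CNTF in the MHC class I, MHC class II, interferon, chemokine and T and NK cell lists by camera, of which the T and NK call alone held with an estimated correlation (adjusted p = 0.0268, others 0.0635 to 0.202). Without crush AAV-CNTF replicate 4 the highest adjusted camera p of the 5 lists was 0.000131, with the preset correlation. That test cannot decide on this library alone, since most of these calls did not hold with an estimated correlation. The levels per library argue against replicate 4 alone for MHC class I and, at low levels, for T and NK cells. Both were higher in 5 of 5 AAV-CNTF libraries than in every AAV-null library. For MHC class II, interferon and chemokines 4 of 5 were. Greater depth of the AAV-CNTF libraries is argued against. With all libraries thinned to the smallest total the highest adjusted camera p was 5.58e-06 (chemokines, 7.68e-06 unthinned). More T or NK cells in the nerve stay open. Their list was 2.33 higher (log2 CPM), but it is itself 1 of the 5, and an effect within resident cells was not tested. By edgeR 0 of its 8 tested genes passed over all genes, while DESeq2 called Lck. The level filter behind the listed genes may also favour genes that are high in 1 group. In the model that also holds the sham libraries, 1 of 100 splits of the 10 crush libraries gave as many genes for CNTF. It was the real one (8, highest other 4). With only the 10 crush libraries 1 gene passed, and 3 of 100 splits, the real one included, gave as many (highest other 15). At an unadjusted p under 0.05, 3 other splits had more genes (1111, 1123 and 1319) than the real one (1091). The answer thus depends on the model and the threshold, and chance is not excluded for the CNTF count. The split with 15 gave 0 in the model with sham, so whether it points to a structure of the samples other than the virus stays untested.

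Crush AAV-null replicate 6 lay apart from its group. An exchange with AAV-CNTF is argued against, since 14 of the 50 top CNTF genes placed it nearer to AAV-CNTF (7 to 13 for the other AAV-null libraries) and its T and NK level was -0.4 log2 CPM against a lowest of 1.09 with AAV-CNTF. An exchange with sham is argued against, with 0 of the 50 top injury genes. Fewer distinct fragments behind its counts stay open: its deviation was 1.31 times the largest of the other 4 for genes of 20 to 100 counts and 0.8 times above 2000 counts, which lies between the bounds set for either outcome. No biological explanation was tested.

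Crush AAV-CNTF replicate 6 lay nearer to AAV-null for 38 of the 50 top CNTF genes fitted without it, against 7 to 14 for the other AAV-CNTF libraries. An exchange with an AAV-null library is argued against, since the highest number placing one of those nearer to AAV-CNTF was 14. A nerve that received little or no CNTF under this label could give the 38, but its STAT3 and MHC class I levels lay 2.73 and 3.63 SD above the AAV-null mean. Its MHC class II, chemokine, interferon and reactive astrocyte levels (4.92, 2.86, 4.16 and 6.67 log2 CPM) lay within the AAV-null range, so that this cannot be told apart from a weaker response.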

How the results depend on the processing

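The pair of libraries left out together and DESeq2 with a fold minimum were chosen after the result was seen. For injury, 1869 to 2099 genes were higher and 1602 to 1852 lower as each library was left out. For CNTF the counts higher and lower were 1 and 0 with only the 10 libraries compared, 15 and 8 with the skeletal muscle covariate, 2 and 0 without both crush AAV-null replicate 6 and crush AAV-CNTF replicate 4. They were 59 and 24 with DESeq2 and 53 and 13 with DESeq2 at 1.5-fold or more. There were 14 higher with replicate as a block and 3 with limma-voom. Leaving out 1 library gave 1 (without crush AAV-CNTF 4) to 38 (without crush AAV-CNTF 6) higher and 0 (without crush AAV-null 2) to 3 (without crush AAV-CNTF 2) lower (each is given with the CNTF genes). The cause was not tested. Lists past the threshold numbered 14, 15 and 16 for injury, CNTF and both together by camera, and 2, 2 and 2 with an estimated correlation. By fry they were 20 for injury, 6 for CNTF and 25 for both together, where fry asks another question than camera. The 6 were the STAT3, CNTF family, MHC class I, MHC class II, chemokine and T and NK cell lists. The relation of CNTF to injury changes was 0.03 to 0.047 under the normalizations and filters, and was not run with DESeq2, limma-voom or a replicate block. The sex covariate and the pseudocount and filter for normalized values were not run.

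Of the values of single genes, 1492 for injury and 1214 for CNTF kept direction and side of the threshold, 6 and 54 passed newly, 8 and 75 no longer passed and 1 and 32 changed sign, each in a gene that had not passed. A value that rounds to 0 was counted as kept, so the CNTF value of Gfap, 0 in the main fit and -0.07 to 0.04 as libraries were left out, is not among the sign changes. Atp2a1 was at 0.2 for injury and 0.13 for CNTF (log2) with the muscle covariate, Hba-a2 at -0.05 with the replicate block and -1.72 with limma-voom, and Lipe at -0.05 and mt-Co1 at -0.01 without both libraries. Leaving out 1 library, the CNTF log2 fold change ranged over -0.84 to 0.64 for Atp2a1, -0.19 to 0.4 for Cntf, -0.06 to 0.07 for Csf3r, -0.23 to 0.09 for Fn1, -0.86 to 1.1 for Hba-a2, and -0.01 to 0.26 for Lipe. It was -0.02 to 0.09 for mt-Co1, -0.17 to 0.03 for Olig2, -0.14 to 0.27 for Rlbp1, -0.07 to 0.24 for Rom1, -0.02 to 0.29 for Tubb3, -0.03 to 0.06 for Vim and -0.13 to 0.2 for Vtn. The cause was not tested. In simulations 23% of genes changed 1.5-fold were recovered, which limits what this number of animals shows for small changes.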

Other observations

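The tests on B cells and on dilution were chosen after the result was seen. Genes sharing a symbol stem were also tested as families of at least 8 members, 211 in each comparison, as hypotheses. After injury histone genes (Hist) rose in 43 of 60, with a median log2 fold change of 2.19 (camera adjusted p = 6.52e-15), and collagen genes (Col) rose in 22 of 33 and fell in 1 (median 1.39; camera adjusted p = 2.67e-07). The Rpl, Tlr, Tnfrsf and Mmp families also passed. With CNTF the interferon-induced GTPases (Gbp) were positive in 9 of 9 (median 2.09; camera adjusted p = 3.2e-09). The Ifi genes were positive in 14 of 14 (median 1.23; camera adjusted p = 4.19e-06). No Gbp or Ifi member passed edgeR's threshold alone. DESeq2 with a fold of at least 1.5 called Gbp2, Gbp4, Gbp7, Gbp8, Gbp9, Ifi203 and Ifi208. Irf, Arid, Ccl and Clec passed too. Of these 6 families 5 had most of their members outside the fixed lists. None of these calls held with an estimated correlation (adjusted p from 0.444 to 0.884), and histone and Gbp paralogs share reads.

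B cells as a source of the higher MHC class II genes with CNTF stay open. The B and plasma cell list differed by 0.18 log2 CPM, within its spread (4.44 ± 0.81 with AAV-null and 4.62 ± 0.96 with AAV-CNTF, SD), and the high level of Igkc would hide a small share of B cells. The fall of glial genes after crush may reflect added phagocyte RNA in part, but 1 common dilution is argued against, since the myelin list fell by 0.83 more than the endothelial list (difference -0.83 ± 0.14 SE, log2). For the gene counts of injury (3912, highest other split 2) and of crush with AAV-CNTF against sham (4437, highest other 29), chance is argued against. In each, 1 of 100 splits, the real one, gave as many, which is the lowest rank these splits can give. The size of the gap adds nothing to that rank, since the other splits mix crushed and sham nerves within their groups.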
